A study of Mus musculus with 8 samples.

How the data were processed

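RNA from intestinal epithelial cells of mice was measured on 8 Affymetrix arrays, 2 in each of 4 genotype groups. The groups, taken from the sample labels, were wild type (WT), mice homozygous for the IKKα AA allele (IKKa-AA), mice with tamoxifen-induced stabilised β-catenin in the intestinal epithelium (bCATca), and mice with both alterations (bCATca_IKKa-AA, called double mutants here). Per the labels' protocols, the mice were on a mixed C57BL/6 x 129Sv x FVB background, tamoxifen was given by gavage on 5 days, cells were prepared 15 days after the first dose, and 200 ng of total RNA per sample was amplified and labelled with biotin.

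The deposited values were linear intensities, 1 per probe set and array. Per the submitters' processing notes, RMA and the affy package were used, with versions and settings not given in the sources used here. RMA corrects background, sets all arrays to a common distribution and summarises probes on a log scale, so the authors' values had been returned to the linear scale before they were deposited. That step is read from the values alone. The design drawn up for this work had assumed log2 values and had foreseen this case, and log2 was taken of every deposited intensity before any test. Median intensities lay between 50.9 and 53.8 on the 8 arrays. The array data carry no read depth, and the number of arrays limits the precision.

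Of 22690 probe sets, 20380 were paired with 1 gene symbol, 691 with several symbols and 1555 with none in the annotation used here, and 64 were controls. Symbols were brought up to date through the Entrez ID for 20351 probe sets and through an accession for 1, and 28 kept the symbol of the platform annotation. The probe set with the highest mean over all 8 arrays stood for a gene, which left 12393 genes, of which 4956 had more than 1 probe set. Probe sets with several symbols or none were tested in a fit of all 22690 probe sets, with p-values adjusted over all of them, and named no gene. The gene encoding IKKα was not analysed here.

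A linear model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with default settings). The residual degrees of freedom were 4 and the prior degrees of freedom 4.28. The comparisons were bCATca against WT, IKKa-AA against WT, double mutants against bCATca, double mutants against IKKa-AA, and the interaction, which is the β-catenin effect in IKKa-AA mice minus that in mice with normal IKKα. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all 12393 genes. Nothing in the labels says that the replicates of a group came from separate animals. The sex chromosome genes differ between the WT arrays, which were therefore not repeats of the same animal, and for the other groups this was not determined, so the p-values measure the spread between these samples, which in those groups may be technical. Replicate numbers were not used to pair samples. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

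Before the data were examined, 35 lists of genes, the comparisons, the tests, the rule for named genes and the alternatives were fixed. Pathway lists covered Wnt targets, mitosis, DNA replication, ribosome biogenesis, Notch, interferon response, antigen presentation, NF-κB targets, antimicrobial defence, endoplasmic reticulum stress, p53 and apoptosis, PPAR and fatty acid oxidation, cholesterol synthesis, glycolysis and hypoxia, xenobiotic metabolism, and extracellular matrix and mesenchymal transition. Epithelial lists covered stem cells, enterocytes, goblet, Paneth, enteroendocrine and tuft cells, and small intestinal and colonic regions. Markers of other cell types covered T cells and intraepithelial lymphocytes, myeloid cells, neutrophils, B and plasma cells, stroma, endothelium, pancreatic acinar cells and erythroid cells. Further lists held handling stress genes, sex chromosome genes and the altered genes, of which Ctnnb1 was read and the gene encoding IKKα was not, and were read per array. Tests were run on the 32 lists other than these, all with at least 5 measured members.

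Lists were tested with camera at its preset correlation of 0.01, with p-values adjusted over the 32 lists of a comparison. Camera with a correlation estimated from the data and fry were run as alternatives. Some genes stood in more than 1 list: Wnt targets and stem cells shared 4, interferon response and antigen presentation shared 3, and antimicrobial defence and neutrophils shared 2. Every other pair of tested lists shared at most 1. For each list, members past the test over all genes were counted, and again with p-values adjusted over the list alone.

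Genes were named by rule: Ctnnb1 in every array, the 6 largest increases and the 6 largest decreases among genes past the test (all of them where fewer passed, and the 3 with the smallest p where none did), and up to 3 members of each list described, or the member with the smallest p where none passed. Where no gene passed in a direction, the rule was applied to that direction alone. For the interaction the rule also named every member of the Wnt and interferon lists. These are described as lists and not gene by gene, which was decided after many of their signs were seen to turn. Predicted genes were left out of the largest changes.

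The alternatives were the mean of a gene's probe sets, every probe set tested, only genes above the median mean level, eBayes with trend and robust settings, array weights, cyclic loess or quantile normalisation of the deposited values, the replicate number as a block, a further threshold of 1 on the log2 scale, an adjusted p under 0.1, only the 4 arrays of the groups compared, and each of the 8 arrays left out in turn. Where an array was left out, the remaining array of its group was assumed to vary like the other groups.

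The model was tested on simulated data: in each of 5 runs per comparison, 200 of 12393 simulated genes were changed. A change of 1 on the log2 scale was recovered in 80.4% of genes for bCATca against WT, 80.4% for IKKa-AA against WT, 78.8% for double mutants against bCATca, 82.4% for double mutants against IKKa-AA and 35.6% for the interaction. A change of 2 was recovered in 99.6%, 98.8%, 98.8%, 99.2% and 94.4%, in the same order. False calls made up 5.73% to 7.09% of all calls. A simulated shift of the Wnt list by -1 in double mutants against bCATca was called in 20 of 20 runs, and 0.5% of unshifted lists were called. The simulated genes varied independently, so the list test was not tried on correlated genes. All groups were simulated with the same spread for a gene. In the data the SD of the difference between replicates was 0.431 in IKKa-AA, against 0.292 in WT. Recovery in comparisons with IKKa-AA was therefore not tried at the spread of that group.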

Results

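Gene expression was measured in intestinal epithelial cells of mice in a model of early Wnt-driven tumour growth, in which β-catenin, the transcriptional effector of Wnt signalling, is stabilised in the gut epithelium by tamoxifen. The series asked what part IKKα plays in the expansion of crypts that follows. IKKα is a kinase of the NF-κB pathway, and the AA allele replaces residues needed for its activation. There were 4 groups of 2 arrays each: WT, IKKa-AA, bCATca and bCATca_IKKa-AA (double mutants). Values are log2 intensities, changes are differences of log2 group means with the standard error (SE) of the model, and n = 2 arrays per group throughout. Adjusted p-values for genes come from limma over 12393 genes, and those for lists from camera over 32 lists.

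Ctnnb1, which encodes β-catenin, was close to the same level on every array. It read 11.96 and 12.29 in WT, 12.14 and 12.31 in IKKa-AA, 12.34 and 12.37 in bCATca, and 12.35 and 12.31 in double mutants. None of the comparisons passed for it: bCATca exceeded WT by 0.23 (SE 0.15, adjusted p = 0.340; 0.0674 without WT replicate 1 and 0.40 without WT replicate 2) and double mutants differed from bCATca by -0.03 (adjusted p = 0.944). Where its 3 probe sets lie relative to the altered part of the gene was not determined here, and stabilisation acts on the protein, so these levels check no label.

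Principal components were taken over the 6196 genes above the median level, and the first held 56.3% of their variance. On that component the replicates stood at -24.8 and -28.9 in WT, 10.5 and 9.65 in double mutants, 12.2 and 28.9 in bCATca, and 10.7 and -18.3 in IKKa-AA, the widest gap. There bCATca replicate 1 lay nearer to the double mutants than to its own replicate. The second component set them apart, with bCATca at 16.1 and 15.5 and double mutants at -13.2 and -15.5. Across genes, bCATca replicate 1 correlated best with bCATca replicate 2 (r = 0.9914). IKKa-AA replicate 1 correlated best with double mutant replicate 2 (r = 0.9927 across genes) and IKKa-AA replicate 2 with WT replicate 2 (r = 0.9936). Genes are not independent replicates, and these coefficients only order the arrays. The SD of the difference between replicates over all genes was 0.431 in IKKa-AA, against 0.292 in WT, 0.336 in bCATca and 0.304 in double mutants. In IKKa-AA, 392 genes differed more than 2-fold between the replicates. The control probe set for 18S ribosomal RNA was lowest in WT (11.31 and 11.69), highest in IKKa-AA (12.39 and 12.35), and between them in bCATca (11.97 and 12.15) and double mutants (11.77 and 12.07), so it moved with every comparison against WT.

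Transcripts read as absent gave a rough guide to the background of the arrays, chosen after the values were seen. The Y chromosome genes Eif2s3y, Kdm5d and Uty read 2.02, 2.30 and 2.56 on WT replicate 1, where the X-inactivation transcript Xist was high, and Xist read 3.56 to 4.03 on the other arrays, where the Y genes were high. Group means up to 4.03 are therefore called near background below, and the size of a change from or to such a level was not determined, so its value is a difference of readings and not an exact fold.

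**Figure D1:**
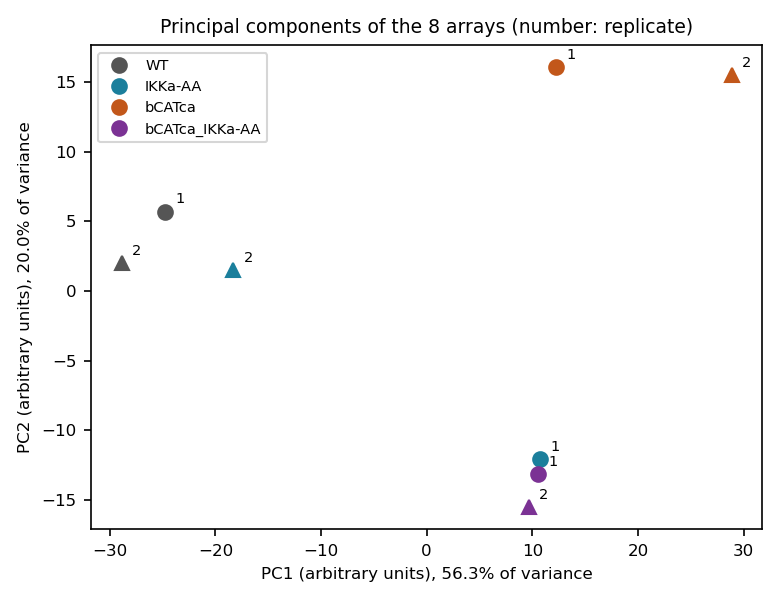
The 8 arrays on the first and second principal components (arbitrary units, 56.3% of the variance on the first), coloured by group, with circles for replicate 1 and triangles for replicate 2. IKKa-AA replicate 1 lies at 10.7 on the first component, beside the double mutants at 10.5 and 9.65, and IKKa-AA replicate 2 at -18.3, nearer to WT.

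What stabilised β-catenin changed in epithelial cell preparations with normal IKKα was asked by setting bCATca against WT. The largest increases were those of Ifitm1, an interferon-inducible membrane protein, by 6.59 (SE 0.37, 96.2-fold, adjusted p = 0.000157), Sox17, an endodermal transcription factor, by 6.58 (SE 0.40, adjusted p = 0.000163), and Myl9, a myosin light chain, by 5.42 (SE 0.22, adjusted p = 5.09e-05). Bex1 rose by 5.17, Fstl1 by 4.42 and Anxa10 by 4.10. The WT levels of Sox17 (3.27), Myl9 (3.33), Bex1 (2.67) and Fstl1 (2.86) were near background. The sugar transporter genes Slc5a4b and Slc5a4a were among the largest decreases, with -5.68 (SE 0.63, adjusted p = 0.00221) and -4.47. Cyp2c29, a cytochrome P450, changed by -5.63 (SE 1.38, adjusted p = 0.0421), Ugt2b5, a glucuronosyltransferase, by -5.11, Cubn, a receptor for vitamin B12 uptake, by -4.80, and Aldh1a1, a retinaldehyde dehydrogenase, by -4.45.

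Wnt targets were the list with the clearest rise: 16 of 28 measured members rose and none fell (18 rose adjusted over the list alone), with a median change of 1.32 and a list adjusted p = 2.0e-12. Of the 16, Prox1 and Wif1 were near background in all 4 groups. The list gave adjusted p = 0.164 with an estimated correlation, and 0.00192 with fry. Among them Notum, a secreted Wnt inhibitor, rose by 3.24, Tnfrsf19, a receptor of stem cells, by 3.15 with 2 of its 3 probe sets in that direction, and Nkd1, a feedback inhibitor of the pathway, by 3.04 from a level near background (3.40). Of 16 stem cell genes, 8 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.90, list adjusted p = 6.1e-05, adjusted p = 0.644 with an estimated correlation). Igfbp4 rose by 3.82 and Prom1 by 2.01. Fry called this list too (adjusted p = 0.0201).

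Of 26 genes of xenobiotic metabolism, 16 fell and none rose (23 lower and 1 higher adjusted over the list alone, median -2.23, list adjusted p = 2.0e-12, adjusted p = 0.644 with an estimated correlation), with Ces2a, a carboxylesterase, at -4.20 beside Cyp2c29 and Ugt2b5. Of 26 enterocyte genes, 8 fell and none rose (15 fell adjusted over the list alone, median -0.71, list adjusted p = 4.1e-10, adjusted p = 0.644 with an estimated correlation). They included Apoc3, an apolipoprotein, at -2.41, Ace at -1.82 and the peptide transporter Slc15a1 at -1.79. In the PPAR and fatty acid oxidation list, 6 of 23 genes fell and 1 rose (12 and 1 adjusted over the list alone, median -0.51, list adjusted p = 7.7e-05, adjusted p = 0.644 with an estimated correlation), among them Slc27a2 at -2.38, Ppara at -1.47 and Acaa2 at -1.22.

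In ribosome biogenesis 7 of 27 genes rose (18 adjusted over the list alone, median 0.70, list adjusted p = 4.7e-08, adjusted p = 0.644 with an estimated correlation), with Nhp2 at 1.16, Nop56 at 1.01 and Gar1 at 0.99. In DNA replication 6 of 28 rose (16 adjusted over the list alone, median 0.51, list adjusted p = 1.9e-06, adjusted p = 0.644 with an estimated correlation), with Gins1 at 1.11, Cdc6 at 1.04 and Mcm7 at 0.96. The mitosis list was called higher with a median of 0.56 (list adjusted p = 6.1e-05, adjusted p = 0.677 with an estimated correlation), although none of its 28 members passed, nor any adjusted over the list alone. Kif2c, its member with the smallest p, stood at 1.09 (adjusted p = 0.0674, 2 of 4 probe sets in that direction). The limma count at an unadjusted p under 0.05 over all genes was 3648.

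Of 41 interferon response genes, 5 rose and none fell in bCATca (9 adjusted over the list alone, median 0.64, list adjusted p = 1.5e-06, adjusted p = 0.644 with an estimated correlation), with the chemokine Cxcl9, near background in WT, at 3.16, Ifit2 at 2.49 and Rsad2 at 1.95. Cxcl9 stood at 2.07 without bCATca replicate 2. T cell markers went the other way: the list was called lower with a median of -0.69 (list adjusted p = 0.00295, adjusted p = 0.644 with an estimated correlation), and none of its 21 members passed, nor any adjusted over the list alone. Cd4, the member with the smallest p, differed by -0.57 (adjusted p = 0.0624).

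The remaining 22 lists were not called in bCATca against WT. Enteroendocrine genes went both ways (2 of 25 higher and 7 lower, 5 and 7 adjusted over the list alone, median -0.12). The hormone genes Gcg, Nts and Sst fell by 2.32, 1.97 and 1.90, Gcg to a level near background. Paneth cell genes had a median of 0.15 with 3 of 10 higher and 1 lower, Pla2g2a at 3.69 and Mmp7 at 1.89. Antimicrobial defence had 4 of 23 higher and none lower (median 0.26, list adjusted p = 0.0738), with Retnlb at 3.56 and Lcn2, near background in WT, at 2.63. Glycolysis and hypoxia had 6 of 20 higher (median 0.24), among them Hk2 at 2.31 and Car12 at 2.15. Medians of the other lists were 0.45 for cholesterol synthesis, 0.16 for antigen presentation, 0.14 for B and plasma cells, 0.03 for NF-κB targets, -0.01 for extracellular matrix, -0.02 for myeloid cells, -0.03 for goblet cells, -0.06 for the colonic region and -0.07 each for endothelium and for p53 and apoptosis. They were -0.09 for endoplasmic reticulum stress, -0.12 each for Notch and the small intestinal region, -0.15 for neutrophils, -0.17 for erythroid cells, -0.19 for tuft cells and -0.20 each for stroma and pancreatic acinar cells. The stroma list was called by fry alone (adjusted p = 0.0359). For NF-κB targets and myeloid cells the direction of the camera test was opposite to the median.

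In all, 1151 genes passed in bCATca against WT, 711 higher and 440 lower, and 543 of them changed at least 2-fold. With cyclic loess the split was 560 higher and 520 lower, and with quantile normalisation 551 and 518. The count was 273 without WT replicate 1, 243 without WT replicate 2, 724 without bCATca replicate 1, 223 without bCATca replicate 2, 1885 without either IKKa-AA array and 699 without either double mutant array. In every one of these 8 fits 169 genes passed, among them Ifitm1, Sox17, Myl9, Bex1, Fstl1, Slc5a4b, Slc5a4a, Notum, Tnfrsf19, Nkd1, Igfbp4, Prom1, Pla2g2a, Car12, Gcg and Nts, while every other gene named above as higher or lower lost its call in at least 1 fit. The largest such adjusted p was 0.229, for Cxcl9 without WT replicate 2. All 10 list calls held in the 8 fits, the weakest being that of T cell markers (highest adjusted p = 0.0483).

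**Figure D2:**
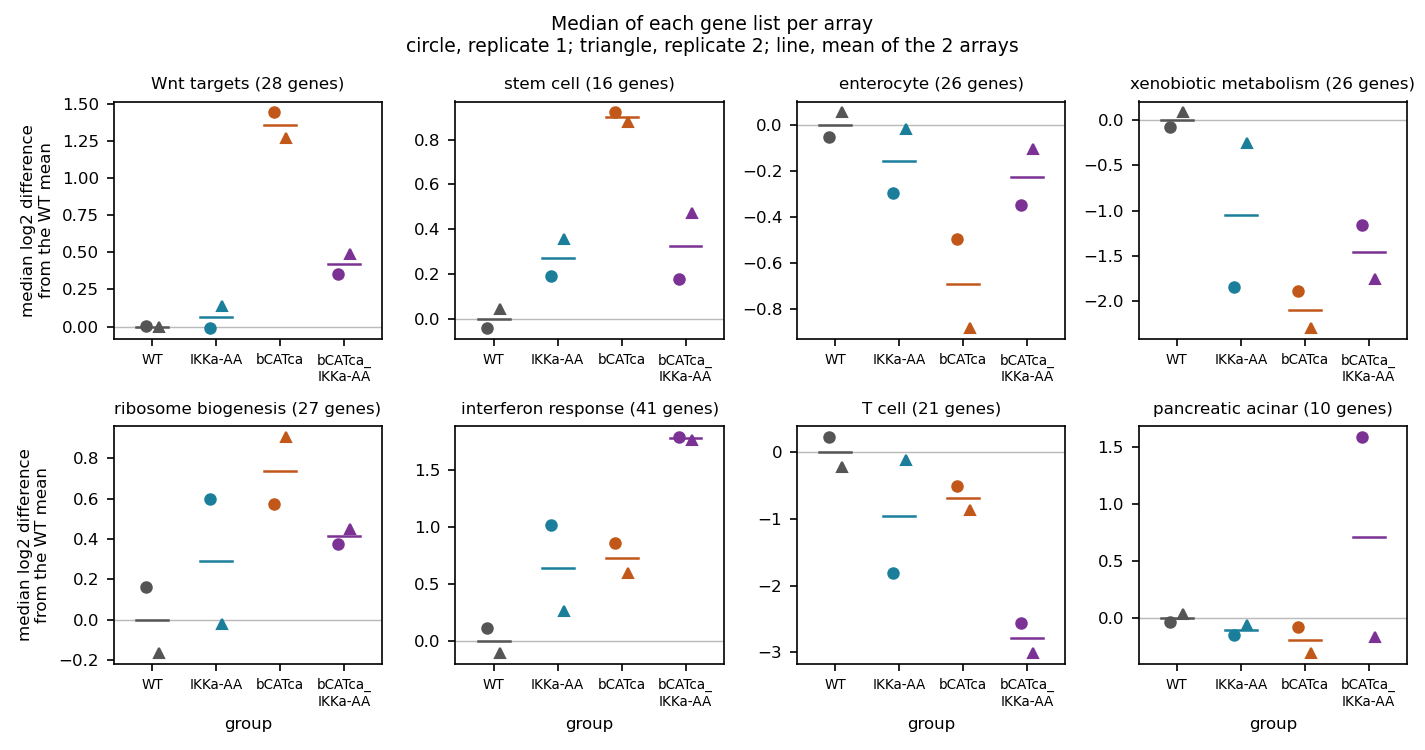
Medians of 8 gene lists on each array, as log2 differences from the WT mean, with circles for replicate 1, triangles for replicate 2 and lines for the mean of the 2 arrays. Wnt targets stand at 1.44 and 1.27 in bCATca and 0.36 and 0.49 in double mutants, and the xenobiotic and T cell medians of the IKKa-AA arrays lie far apart.

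The effect of the IKKα AA allele without stabilised β-catenin was asked by setting IKKa-AA against WT. A single gene passed: Amph, which encodes the membrane-bending protein amphiphysin, fell by 2.21 (SE 0.17, adjusted p = 0.0108), from 4.63 in WT to 2.42, a level near background. No gene rose past the test. The genes with the smallest p among those with higher values were Ly96, a cofactor of lipopolysaccharide sensing, at 2.15 (SE 0.33, adjusted p = 0.147), Casp4 at 1.29 (adjusted p = 0.147) and the Wnt receptor gene Fzd7 at 1.07 (adjusted p = 0.125, 1 of 2 probe sets in that direction). At an unadjusted p under 0.05, limma gave 1449 genes.

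No member of any list passed in IKKa-AA against WT, and 17 lists were called, 10 higher and 7 lower. Interferon response had a median of 0.61 (1 of 41 higher adjusted over the list alone, list adjusted p = 6.2e-11, adjusted p = 0.490 with an estimated correlation), with Zbp1 at 1.16 (adjusted p = 0.236). Antigen presentation had a median of 0.46 (1 of 18 adjusted over the list alone, list adjusted p = 6.5e-05, adjusted p = 0.490 with an estimated correlation), and xenobiotic metabolism a median of -1.13 (0 of 26 adjusted over the list alone, list adjusted p = 2.7e-08, adjusted p = 0.490 with an estimated correlation), with Gsta2 at -1.86 (adjusted p = 0.306). These 3 lists stayed called in all 8 fits with an array left out. The others called higher were mitosis (median 0.36), ribosome biogenesis (0.29), stem cells (0.28, 4 of 16 adjusted over the list alone), endoplasmic reticulum stress (0.27), antimicrobial defence (0.23), cholesterol synthesis (0.23), DNA replication (0.21) and glycolysis and hypoxia (0.13), each at an adjusted p of at least 0.490 with an estimated correlation. Those called lower were T cells (-0.94), PPAR and fatty acid oxidation (-0.25), endothelium (-0.20), stroma (-0.19), neutrophils (-0.14) and p53 and apoptosis (-0.13). Each of the 17 gave an adjusted p of at least 0.490 with an estimated correlation, and fry called 0.

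The IKKa-AA arrays differed from each other in these same lists. Relative to the WT mean, replicates 1 and 2 had medians of -1.85 and -0.25 for xenobiotic metabolism, -1.81 and -0.12 for T cells, 1.01 and 0.26 for interferon response, and 0.79 and -0.04 for mitosis. Without replicate 1, 8 lists were called and 1 gene passed. Without replicate 2, 17 lists were called and 325 genes passed. Counts were 6 and 7 without WT replicate 1 and 2, and 0 when any bCATca or double mutant array was left out. Amph lost its call in those 4 fits (highest adjusted p = 0.0711, without double mutant replicate 1). Without IKKa-AA replicate 1 the calls ended for T cells (adjusted p = 0.124), PPAR and fatty acid oxidation (0.124), DNA replication (0.502), ribosome biogenesis (0.762), endoplasmic reticulum stress (0.620), glycolysis and hypoxia (0.571), antimicrobial defence (0.0896), endothelium (0.0896) and p53 and apoptosis (0.183), and the direction turned for mitosis (0.571) and cholesterol synthesis (0.861). Without replicate 2 they ended for neutrophils (0.407), endothelium (0.202), stroma (0.0726) and stem cells (0.0629). Without WT replicate 1 they ended for cholesterol synthesis (0.976), glycolysis and hypoxia (0.0686), endothelium (0.0633), stroma (0.0549) and endoplasmic reticulum stress (0.0536), and without WT replicate 2 for p53 and apoptosis (0.213), endothelium (0.0855), neutrophils (0.0803), mitosis (0.0706) and glycolysis and hypoxia (0.0533). Without either double mutant array the call of p53 and apoptosis ended (0.0719).

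How epithelial cell preparations with stabilised β-catenin differed with the IKKα AA allele was asked by setting double mutants against bCATca. Slc23a1, a vitamin C transporter, rose by 3.08 (SE 0.29, adjusted p = 0.00897) from a level near background in bCATca (3.58), Pmp22 by 2.99, the sugar transporter gene Slc5a4a by 2.78 and Per2, a component of the circadian clock, by 2.20 (SE 0.23, adjusted p = 0.0134). Oas2, an oligoadenylate synthetase induced by interferon, rose by 2.06 and Ifi27l2a by 1.99. Several genes that were highest in bCATca against WT were among the largest decreases: Myl9 fell 12.1-fold (SE 0.22 on the log2 scale, adjusted p = 0.00152), Sox17 by 3.27 and Ifitm1 by 3.14. Both comparisons use the same 2 bCATca arrays, with opposite sign. Errors of these arrays alone therefore push genes and lists that are high in the first comparison lower in the second. Clu, which encodes clusterin, changed by -3.25. Igha, the heavy chain of immunoglobulin A, fell by 5.96 (SE 1.07, adjusted p = 0.0444) and Ccl5, a chemokine of T cells, by 4.14 (SE 0.55, adjusted p = 0.0180). Both are transcripts of immune cells, and the AA allele is in all cells. A different share of such cells in the samples and a change within cells were not told apart.

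The Wnt target list was called lower in double mutants than in bCATca: 4 of 28 fell and none rose (11 adjusted over the list alone, median -0.57, list adjusted p = 4.7e-11, adjusted p = 0.203 with an estimated correlation). Nkd1 fell by 2.16 (SE 0.15, adjusted p = 0.00192), Notum by 2.04 and Apcdd1, another Wnt inhibitor, by 1.25. Fry gave adjusted p = 0.0189 for this list, the only list it called here. Of 16 stem cell genes, 2 fell (6 lower and 1 higher adjusted over the list alone, median -0.50, list adjusted p = 0.000706, adjusted p = 0.435 with an estimated correlation), Igfbp4 by 1.32 and Prom1 by 1.06. Enterocyte genes were called higher (1 of 26, 7 adjusted over the list alone, median 0.56, list adjusted p = 1.2e-08, adjusted p = 0.578 with an estimated correlation), with the peptidase gene Enpep at 1.02, and xenobiotic metabolism likewise (0 of 26, 2 higher adjusted over the list alone, median 0.54, adjusted p = 0.642 with an estimated correlation).

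**Figure D3:**
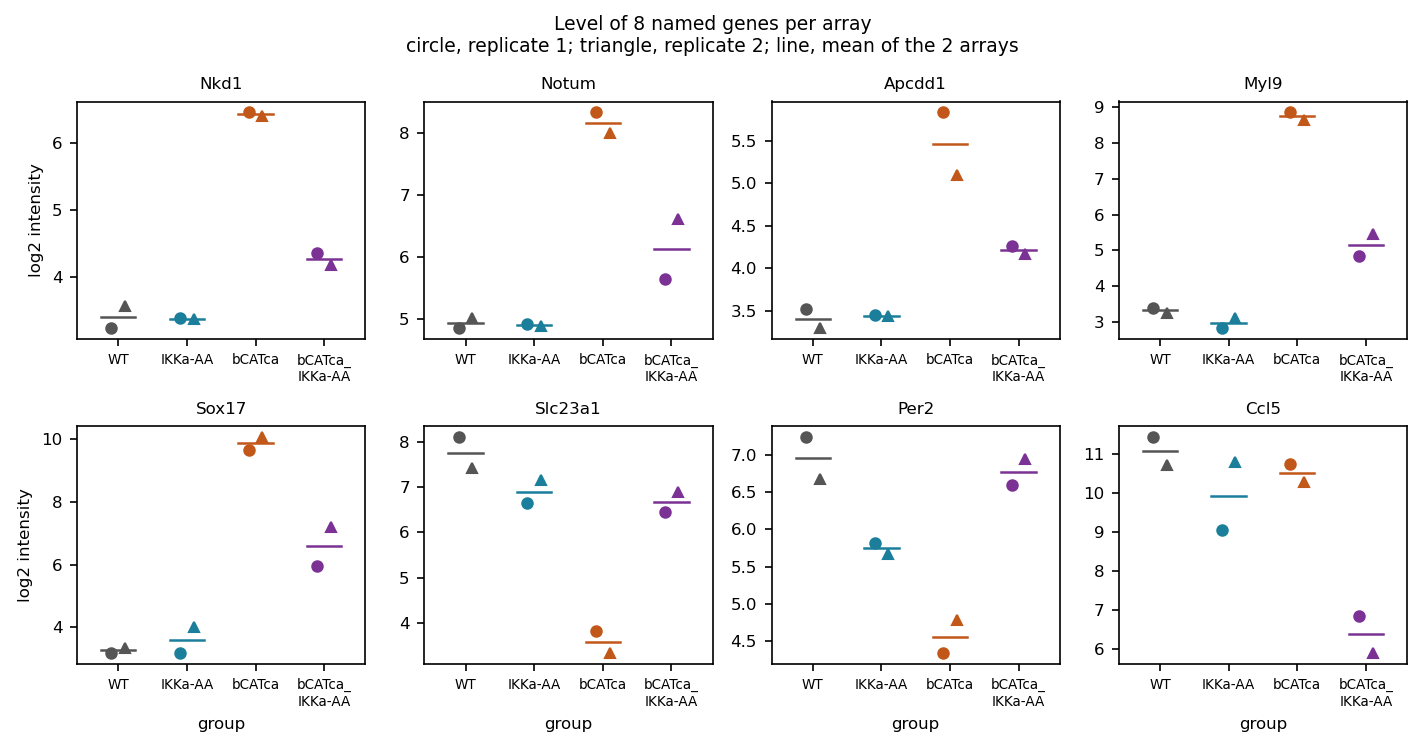
Log2 intensities of 8 named genes on each array, with circles for replicate 1, triangles for replicate 2 and lines for the mean of the 2 arrays. Nkd1 averages 6.44 in bCATca, 4.27 in double mutants and 3.40 in WT, and Ccl5 averages 6.37 in double mutants against 9.93 to 11.08 in the other groups.

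Of 41 interferon response genes, 3 rose and none fell in double mutants against bCATca (22 adjusted over the list alone, median 0.97, list adjusted p = 3.8e-17, adjusted p = 0.435 with an estimated correlation), with Oasl2 at 1.48 and Mx1 at 1.39 beside Oas2. The T cell list was called in the opposite direction, and 1 of its 21 members fell, Ccl5 (14 adjusted over the list alone, median -2.10, list adjusted p = 2.1e-09, adjusted p = 0.435 with an estimated correlation), and B and plasma cell markers were called lower (1 of 13, 3 adjusted over the list alone, median -0.20, adjusted p = 0.435 with an estimated correlation), with Ms4a1 at -1.14, near background in double mutants. Relative to the WT mean, the T cell medians were -2.57 and -3.01 in the double mutant arrays and -0.50 and -0.86 in the bCATca arrays. Whether the share of T cells, B cells or plasma cells in the samples differed was not tested. Antigen presentation (0 of 18, median 0.41) was called higher and Paneth cells (1 of 10, 4 adjusted over the list alone, median -0.91, Pla2g2a at -1.48) lower. Each of the last 2 lists gave adjusted p = 0.435 with an estimated correlation.

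Endoplasmic reticulum stress genes were called higher in double mutants (2 of 23, 4 adjusted over the list alone, median 0.15), with Herpud1 at 1.19 and Trib3 at 0.97, and the adjusted p was 0.578 with an estimated correlation. DNA replication (median -0.34) and ribosome biogenesis (median -0.28) were called lower with no member past the test, at adjusted p = 0.602 and 0.642 with an estimated correlation. Pancreatic acinar genes were called higher (0 of 10, median 0.88), on the strength of double mutant replicate 1, where the median was 1.59 above the WT mean, against -0.16 in replicate 2. Their adjusted p was 0.642 with an estimated correlation, and it was 0.958 without double mutant replicate 1 and 0.0930 without bCATca replicate 2.

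In double mutants against bCATca 150 genes passed, 50 higher and 100 lower, 111 of them by at least 2-fold, and 13 lists were called. Counts were 61 without either WT array, 395 without either IKKa-AA array, 16 and 17 without bCATca replicate 1 and 2, and 11 and 35 without double mutant replicate 1 and 2. In all 8 fits 5 genes passed: Myl9 and Nkd1, and Hacd4, Hs6st2 and P4ha2, which were named for this after their values were seen. Every other gene named here as higher or lower lost its call in at least 1 fit, for example Slc23a1 without double mutant replicate 1 (adjusted p = 0.0559), Igha (0.254) and Prom1 (0.254) in the same fit, and Igfbp4 without bCATca replicate 2 (0.230). The calls of Wnt targets, stem cells, interferon response, T cells, B and plasma cells, Paneth cells, enterocytes and antigen presentation held in all 8, and those of xenobiotic metabolism, ribosome biogenesis, DNA replication and endoplasmic reticulum stress each ended in 1 fit, the first 3 without bCATca replicate 2 (adjusted p = 0.220, 0.184 and 0.0654) and the last without bCATca replicate 1 (0.0576).

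The effect of stabilised β-catenin in epithelial cell preparations with the IKKα AA allele was asked by setting double mutants against IKKa-AA. Of the 7 genes that passed, 6 were higher: Ifit2 by 3.46 (SE 0.38, adjusted p = 0.0366), Ifitm1 by 3.45 (SE 0.37), Bex1 by 2.83, Ifi27l2a 5.65-fold, Myl9 by 2.19 and Hs6st2, a heparan sulfate sulfotransferase, by 1.42. Isl1, a transcription factor of endocrine cells, fell by 1.36 (SE 0.16, adjusted p = 0.0444) to a level near background. The IKKa-AA levels of Bex1 (2.40) and Myl9 (2.96) were near background, and Hs6st2 was near background in both groups (2.53 and 3.95). At an unadjusted p under 0.05, limma gave 859 genes.

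Interferon response was the list with the smallest p in this comparison: 1 of 41 genes rose (28 adjusted over the list alone, median 1.15, list adjusted p = 4.9e-28, adjusted p = 0.367 with an estimated correlation). T cell markers were called lower (0 of 21, 11 adjusted over the list alone, median -1.66, list adjusted p = 2.8e-14, adjusted p = 0.367 with an estimated correlation), and Ccl5 differed by -3.55 (adjusted p = 0.137). Wnt targets were called higher (0 of 28, 8 adjusted over the list alone, median 0.34, list adjusted p = 5.8e-07, adjusted p = 0.367 with an estimated correlation), with Nkd1 at 0.90 (adjusted p = 0.208). Those 3 calls held in all 8 fits with an array left out. The other lists called were pancreatic acinar cells (median 1.01), neutrophils (0.22), antimicrobial defence (0.21) and endothelium (0.19) as higher, and tuft cells (-0.39), xenobiotic metabolism (-0.29), goblet cells (-0.15) and B and plasma cells (-0.08) as lower. Their adjusted p was at least 0.367 with an estimated correlation, and fry called 0 of all 11.

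This comparison rested on the discordant IKKa-AA arrays: 159 genes and 16 lists passed without IKKa-AA replicate 1, and 5 genes and 12 lists without replicate 2. Counts of genes were 0 without any WT or bCATca array, and 3 and 7 without double mutant replicate 1 and 2, and none of the 7 genes passed in every fit (highest adjusted p = 0.392, for Ifi27l2a without double mutant replicate 1). Without IKKa-AA replicate 2, xenobiotic metabolism was called higher (adjusted p = 0.0292), and the calls ended for tuft cells (0.707), neutrophils (0.285), antimicrobial defence (0.277), B and plasma cells (0.171) and endothelium (0.0589). Without IKKa-AA replicate 1 they ended for pancreatic acinar cells (0.131), goblet cells (0.121) and endothelium (0.0667). Without double mutant replicate 1 the direction turned for pancreatic acinar cells (0.649), and the calls ended for goblet cells (0.179), neutrophils (0.122) and endothelium (0.115). Without double mutant replicate 2 they ended for B and plasma cells (0.254), tuft cells (0.238), antimicrobial defence (0.231), neutrophils (0.112) and xenobiotic metabolism (0.112), and without either WT array for B and plasma cells (0.0523), goblet cells (0.0506) and neutrophils (0.0506).

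Whether the IKKα AA allele altered the β-catenin effect itself was asked by the interaction, and 11 genes passed, 5 with a positive and 6 with a negative value. The value was positive for Slc23a1 by 3.95 (SE 0.41, adjusted p = 0.0166), Per2 by 3.42, the peroxisomal oxidase gene Acox2 by 3.37, the carboxylesterase gene Ces1f by 2.08 and Amph by 2.04. Amph stood at 4.63 in WT and near background in IKKa-AA, bCATca and double mutants (2.42, 2.44 and 2.28), so no β-catenin effect could be measured for it with the AA allele, and its value restates the fall from WT. The value was negative for Myl9 by -3.23 (SE 0.31, adjusted p = 0.0166), Hacd4 by -2.35, Hs6st2 by -2.21, Nkd1 by -2.14, Marcksl1 by -1.81 and Fzd7 by -1.58, the last with 1 of 2 probe sets in that direction. Myl9, Hs6st2 and Nkd1 were near background in both WT and IKKa-AA, Hs6st2 also in double mutants (3.95), and Slc23a1 in bCATca. At an unadjusted p under 0.05, limma gave 1950 genes.

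Wnt targets as a list had a negative interaction: 25 of 28 members were negative and 2 passed, Nkd1 and Fzd7 (13 adjusted over the list alone, median -0.94, list adjusted p = 5.2e-09). The list gave adjusted p = 0.278 with an estimated correlation and 0.0369 with fry. Stem cells (median -0.94, 9 of 16 negative and 1 positive adjusted over the list alone), ribosome biogenesis (-0.62), mitosis (-0.56), DNA replication (-0.54) and Paneth cells (-0.41) were also called negative, each at an adjusted p of at least 0.539 with an estimated correlation. Xenobiotic metabolism (1.65, 4 of 26 adjusted over the list alone), pancreatic acinar cells (1.21), PPAR and fatty acid oxidation (0.55), enterocytes (0.55, 4 of 26 adjusted over the list alone), stroma (0.33, fry adjusted p = 0.0411), neutrophils (0.32) and interferon response (0.25) were called positive. No member of those lists passed over all genes, and all 13 gave an adjusted p of at least 0.278 with an estimated correlation. For T cell markers the median was -0.88 and the list was not called (adjusted p = 0.0752).

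The interferon call (list adjusted p = 0.0412, 0.774 with an estimated correlation, 0 of 41 adjusted over the list alone) ended without WT replicate 1 (0.254), double mutant replicate 1 (0.0923) and double mutant replicate 2 (0.0582), and without IKKa-AA replicate 2 the direction of its test turned (0.502). Calls also ended for pancreatic acinar cells in 6 fits (highest adjusted p = 0.473, without double mutant replicate 1), Paneth cells in 4 (0.419, without IKKa-AA replicate 2), stroma in 3 (0.0625, without WT replicate 1), neutrophils in 2 (0.198, without IKKa-AA replicate 2), mitosis without IKKa-AA replicate 1 (0.141), and PPAR and fatty acid oxidation without bCATca replicate 2 (0.0674). Those of Wnt targets, stem cells, xenobiotic metabolism, enterocytes, DNA replication and ribosome biogenesis held in all 8. The interaction count was 0 without WT replicate 1 or either bCATca array, 8 without WT replicate 2, 85 and 234 without IKKa-AA replicate 1 and 2, and 1 and 30 without double mutant replicate 1 and 2, and none of the 11 genes passed in all 8 fits (highest adjusted p = 0.146, for Fzd7 without bCATca replicate 2).

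Across all 12393 genes, the β-catenin effect with normal IKKα and that with the AA allele, which share no array, had a Pearson correlation of 0.395 (Spearman 0.236). Of the 7 genes that passed with the AA allele, 6 also passed in the same direction with normal IKKα, against 0.380 expected of independent lists. Both tests used the same spread estimate for each gene, so the lists were not independent and this expected count may be too low. Without IKKa-AA replicate 1 the correlation was 0.510 and without replicate 2 it was 0.0637. Over the 711 genes that rose in bCATca, the median change was 0.95 with normal IKKα, on which they were chosen, and 0.17 with the AA allele. The IKKα effects without and with stabilised β-catenin had a correlation of -0.0116 across genes (Spearman -0.134). No p-value is given, since genes are not independent replicates.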

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

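The interaction was planned, and every test of an explanation in this part was chosen only after the result it weighs was seen. The interaction test itself drew attention to 11 genes whose β-catenin effect differed in value with the IKKα allele. The difference was 3.95 for Slc23a1, 3.42 for Per2, 3.37 for Acox2, 2.08 for Ces1f and 2.04 for Amph, and -3.23 for Myl9, -2.35 for Hacd4, -2.21 for Hs6st2, -2.14 for Nkd1, -1.81 for Marcksl1 and -1.58 for Fzd7. For Amph it restates the fall from WT, since the gene was near background in the other 3 groups. A signal also stood in data the report does not use: of 2246 probe sets with several gene names or none, 130 passed in bCATca against WT, 70 higher and 60 lower, 10 passed in double mutants against bCATca and 6 in the interaction.

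The Wnt target list was called lower in double mutants than in bCATca. Double mutants carry the IKKα AA allele in all cells, so their cells without stabilised β-catenin would be like IKKa-AA, not WT. A test against cells otherwise like WT therefore cannot decide, since the allele alone could make the genes differ. It asked whether a smaller share of cells with stabilised β-catenin among such cells was the whole cause. Such a mixture would keep the same share of the linear change in every gene, but among the 16 Wnt list members past the test the kept shares ran from 0.116 to 0.719 (Cochran's Q over n = 16 genes against a chi-square distribution, p = 1.8e-08, and 1.4e-08 over the 14 members at least 2-fold apart), and from 0.153 to 0.719 without Apcdd1, Nkd1, Prox1 and Wif1, which were near background in WT (p = 0.000261 over the other 12). Against cells otherwise like IKKa-AA, the heterogeneity p was 0.0353 over the 16 members and 0.158 over the 11 at least 2-fold apart, and without the same 4 genes 0.282 over 12 and 0.379 over the 8 at least 2-fold apart, so that mixture and a change within cells cannot be told apart. This test was first run on the members at least 2-fold apart alone, and the condition that both p-values be under 0.05 was set after they were seen, and the errors of the shares are approximate because RMA values are not strictly linear. A lower Wnt response within cells through IKKα, the biological explanation the design offers, also stays open and was not tested.

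Per2 stood at 7.24 and 6.68 in WT, 5.82 and 5.67 in IKKa-AA, 4.35 and 4.78 in bCATca and 6.59 and 6.95 in double mutants, so it was lowest in bCATca and low in IKKa-AA as well, and the 9 other genes of its clock arm, a list drawn up after Per2 was seen, had medians of -1.38 in bCATca against WT and 1.21 in double mutants against bCATca (for the latter camera p = 4.1e-09, 0.0367 with an estimated correlation). Both clock arm medians use the bCATca arrays, with opposite sign. A different time of day at tissue collection between the groups could not be excluded. Arntl, Npas2, Clock and Nfil3, which peak at the opposite time, had a median of 0.0119 in double mutants against bCATca (spread 0.176). Arntl differed by -0.65 (SE 0.25) and Nfil3 by -0.11, and Npas2 and Clock by 0.13 and 0.18. Genes of the clock arm also differed between replicates. In WT, Dbp read 6.83 and 8.86 and Nr1d1 5.87 and 7.94, while Per1 read 6.59 and 6.55. A difference in time of day within groups was not tested either. A difference in glucocorticoid exposure stays open as well: 10 genes induced by glucocorticoids had a median of 0.689 (camera p = 1.7e-05, 0.0319 with an estimated correlation), which met the condition first set. The 7 genes other than Tsc22d3, Fkbp5 and Sgk1, which had been noticed first, also went that way (median 0.464, camera p = 0.00405, 0.0416 with an estimated correlation) but missed a median of 0.5, a condition added after the values were seen. An effect of stabilised β-catenin or of the IKKα allele on the clock stays open and was not tested.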

How the results depend on the processing

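Every alternative here was planned before the data were examined, and only the choice to describe the Wnt and interferon members of the interaction as lists, not gene by gene, was made after signs were seen to turn. Without each array in turn, the number of genes past the test ran from 223 to 1885 in bCATca against WT, 0 to 325 in IKKa-AA against WT, 11 to 395 in double mutants against bCATca, 0 to 159 in double mutants against IKKa-AA and 0 to 234 in the interaction. Fewer arrays leave fewer degrees of freedom, and leaving out a discordant array lowers the spread all groups share; the cause of each move was not tested further. The lists called ran from 8 to 18 in IKKa-AA against WT and from 7 to 16 in double mutants against IKKa-AA, and stayed within 1.5 times the count in the others. Ctnnb1, which passed nowhere, ran from 0.0674 to 0.40 in bCATca against WT, from -0.0636 to 0.27 in IKKa-AA against WT and from -0.30 to 0.0318 in the interaction. The correlation of the IKKα effects ran from -0.117 to 0.101. In the interaction, 5 of 28 Wnt list members and 25 of 41 interferon list members turned sign in at least 1 of the 8 fits, and neither of the 2 members past the test did.

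For the remaining alternatives the cause of a move was not tested unless named. With the mean of a gene's probe sets, 1 gene passed in double mutants against IKKa-AA, and there Ctnnb1 read -0.0180 and Foxm1 0.0681, neither past the test. With every probe set tested, 1 passed in double mutants against IKKa-AA and 54 in the interaction, over more tests. With only genes above the median, fewer genes were tested, and 0 passed in IKKa-AA against WT, 63 in double mutants against bCATca, 0 in double mutants against IKKa-AA and 45 in the interaction; lists called were 11 in IKKa-AA against WT and 4 in double mutants against IKKa-AA. With trend and robust settings, 4 passed in IKKa-AA against WT and 73 in the interaction. With array weights, 1788 passed in bCATca against WT and 36 in the interaction. Double mutants against IKKa-AA gave 4 genes with cyclic loess and 0 with quantile normalisation. With the replicate number as a block, 701 passed in bCATca against WT, 72 in double mutants against bCATca, 0 in double mutants against IKKa-AA and 6 in the interaction; nothing shows that the numbers pair samples. A further threshold of 1 on the log2 scale left 543 in bCATca against WT. An adjusted p under 0.1 gave, in the order above, 2408, 4, 397, 13 and 148. With only the 4 arrays of the groups compared, 0 passed in IKKa-AA against WT, 331 in double mutants against bCATca and 0 in double mutants against IKKa-AA. Camera with an estimated correlation called 0 lists in all 5 comparisons (0, 0, 0, 0 and 0), and fry called 3, 0, 1, 0 and 2. With 2 arrays per group the p-values rest on a spread shared across groups, and genes near the lower end of the intensities are the least precise.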

Other observations

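Except for the handling stress list, which was planned, the values and tests in this part were chosen after the results were seen. WT replicate 1 read 9.18 for Xist and 2.02 for Eif2s3y, while the other 7 arrays read 3.56 to 4.03 and 7.25 to 7.56. Xist is expressed from the inactive X chromosome of females and Eif2s3y lies on the Y chromosome, and the labels give no sex. By these readings sex was not balanced between WT and the other groups. Its part in the comparisons against WT and in the interaction was not tested apart from that of WT replicate 1 itself. The fit without WT replicate 1 held only arrays with low Xist and high Eif2s3y, but left 1 WT array. Defa31, a defensin of Paneth cells, read 9.44 in WT replicate 1 and 9.58 in bCATca replicate 1, and 4.72 to 5.50 in the other arrays. Hspa1a, a heat shock gene, read 8.39 in WT replicate 1 and 7.47 in double mutant replicate 1, and 4.40 to 5.87 elsewhere. The pancreatic elastase gene Cela2a read 7.28 in double mutant replicate 1 and 3.21 to 3.71 elsewhere.

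The IKKa-AA arrays differed widely, and replicate 1 lay near the double mutants. A wrong label, with stabilised β-catenin present in replicate 1, is argued against. Its median shift from WT over the 16 Wnt list members past the test was 0.0699. The lowest of the 4 arrays labelled with stabilised β-catenin read 0.702, with a spread of 0.109 within groups. No other error of label was tested, such as a replicate 2 without the AA allele. Replicate 2 correlated with WT replicate 2 at r = 0.9936, against 0.9933 between the WT arrays. Degraded RNA in replicate 1 is argued against as well, since the 3' minus 5' difference of actin was 0.451 on that array, within the 0.368 to 0.768 of the others, and that of Gapdh was -0.237, the lowest of the 8. The 18S control read 12.39 on replicate 1, the highest of the 8, and 12.35 on replicate 2, and poor labelling was not tested. The handling stress list, read per array, had medians of 0.015 on replicate 1 and -0.047 on replicate 2, against -0.269 to 0.107 on the other arrays. A difference between the animals or in the cells collected stays open and was not tested, and the design names no biological difference between these samples.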
